A study of Homo sapiens with 29 samples.

How the data were processed

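RNA sequencing counts of 6 in vivo libraries of the glioblastoma line TS895, the guide index of the TKOv3 CRISPR library and guide counts of its plasmid pool were used. The in vivo table, as deposited, holds whole-number read counts per gene for 57445 gene IDs with their symbols, and 5 rows that name no gene. Per the labels' protocols, the culture and library steps are given in the same words for all samples and describe cultured cells and nested PCR of guides, so the in vivo procedure, the host and the RNA library kit are not given in the sources used here. Per the submitters' processing notes, Bowtie, Salmon and DESeq2 were used with the human genome build GRCh38, with no roles or versions given. Which program counted the reads, its annotation and its use of strand are not given in the sources used here. The row names for reads outside genes, ambiguous reads and reads aligned to several places are those of a program that counts uniquely aligned reads per gene. Reads shared between near-identical genes, such as paralogs, would then be left out, and overlapping or antisense genes cannot be told apart where strand was not used. The deposited plasmid table holds read counts per guide with no header and lists guides with 1 or more reads. It was read against the index, and all listed guides were found there.

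The columns of the in vivo table show the group but not the replicate number, so libraries carry the number in their column and were not paired. The groups were vehicle (n = 3) and neratinib at 40 mg/kg (n = 3), both labelled 3 h. Rows naming no gene were left out of library sizes and tests. Of all reads, between 6.71% and 8.81% lay outside genes, between 16.1% and 21.2% aligned to several places, between 1.11% and 1.28% were ambiguous and between 1.03% and 1.57% were not aligned. Gene symbols are those of the table. For list membership, 51488 IDs were matched to current symbols, since tRNA synthetase and some other genes carry older symbols (NARS, YARS) in the table. Levels of genes that could reveal the sex of a donor are not reported.

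Genes were filtered with filterByExpr, scaled with TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) between the 2 groups with no covariate, with Benjamini-Hochberg adjustment and a threshold of adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes. Before the data were examined, 28 gene lists were fixed, covering ATF4 targets, growth factor signalling, lipid synthesis, stress responses, cell cycle, ribosomal and mitochondrial genes, glioblastoma states and markers of other cell types. They were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 27 lists with tested genes, and again with an estimated correlation and with fry, which tests whether a list's genes move on balance in one direction. Fry called 4 lists: mitochondrial genes higher, and cholesterol, neural-progenitor-like and mature oligodendrocyte genes lower.

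The named genes were likewise fixed by rule: the 8 largest rises and the 8 largest falls among genes past the threshold with a mean of at least 50 counts and no overlap between groups, up to 4 members of each list that passed with the lowest p (and 1 in the other direction), the member with the lowest p where none passed, and always EGFR, ERBB2, ERBB3, EIF2AK4 and ATF4. As no gene passed, the text names the member of lowest p of each list, except for 1 list whose member is not reported here. Other genes are said to be named after their values were seen, and the 12 genes called with the GC slope covariate were all named. All guides of EIF2AK4 and the most abundant guide were named.

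GC content was taken from the guides of the index, as the mean over a gene's guides, for 12503 of the 14635 tested genes (85.4%). Guides have between 40 and 75% GC, so the value is a coarse stand-in for transcript GC content, which was not used here. A library's GC slope is the slope of the gene's log2 CPM deviation from its mean over libraries on guide GC content, over genes with a mean log2 CPM of at least 1. The fit with this slope as covariate, the removal of a loess trend on guide GC content (span 0.5), restriction to genes with guide GC content, limma voom with quality weights and the share of reads outside genes as covariate were added after seeing the data.

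The scripts were tested on simulated counts drawn from the means and library sizes of these libraries, with the dispersions of the fit with the GC slope covariate, for 14635 genes, of which 200 and the ATF4 list were changed; the shares below are of the 200. With no GC gradient, 95% of 2-fold and 100% of 4-fold changes were called by the comparison of the groups, with 11 of 14393 unchanged genes called, and 86% and 100% with the GC slope covariate, with 12 unchanged genes called. With a simulated GC gradient as large as the observed one, the comparison of the groups called 79% and 100% of the changes and 1509 unchanged genes, and the fit with the covariate 67% and 92% with 14 unchanged genes. The simulated gradient was a straight line on guide GC content, a form that the covariate takes up by construction. In the data, within-group contrasts still correlated with the trend on guide GC removed, and the comparison of the groups called 0 genes. Its biological coefficient of variation was 0.215, against 0.114 with the covariate. The shares therefore need not hold for the data. The 200 genes were drawn from those with a mean of at least 50 counts.

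Alternatives chosen before the data were examined were DESeq2 1.42.0, limma voom, DESeq2 size factors, library size scaling, other count filters and thresholds, other list tests and leaving out each library in turn. The plasmid pool was summarised by percentiles, the Gini coefficient and the share of low guides (Python 3.11.15, scipy 1.17.1), with bootstrap intervals from 200 draws of guides for the ratio and the coefficient, an exact binomial interval for the share and exact Poisson intervals for single guides. Of 65722 guides whose gene symbol is in a GRCh38.p14 gene table, 99.99% lie on the gene's chromosome and 10.2% inside its interval there, so the index's coordinates are given as deposited and are not in that build. PCR reads without molecular identifiers are not independent molecules.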

Results

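The series addressed the activation of GCN2, the kinase encoded by EIF2AK4 that phosphorylates eIF2 alpha and starts the integrated stress response, by ATP-competitive kinase inhibitors in glioblastoma models. Its 29 samples comprised 11 samples of pooled CRISPR knockout screens in the glioblastoma lines SF268 and SKMG3, 12 RNA samples of SF268 cells labelled LC9B or GCN2cr3, at time 0 or given 675 nM neratinib, and 6 RNA samples of the glioblastoma line TS895 labelled as in vivo. Neratinib is a covalent inhibitor of the receptor tyrosine kinases EGFR, ERBB2 and ERBB4. The 3 vehicle and 3 neratinib (40 mg/kg) in vivo libraries, both labelled 3 h, were compared here, and the guide index and plasmid pool of the TKOv3 knockout library were described. The other 23 samples were not analysed here.

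The in vivo libraries held between 27112316 and 30846903 reads assigned to genes. Vehicle libraries averaged 30028700 ± 1082010 and neratinib libraries 27912600 ± 753412 assigned reads (SD, n = 3 each). The libraries are called by the number in their column, 21, 22 and 23 for vehicle and 24, 25 and 26 for neratinib. No pair of libraries agreed within sampling noise, since the chi-square per degree of freedom over genes was at least 10.2 (neratinib libraries 24 and 25). The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

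The first question was which transcripts differed between neratinib and vehicle in vivo. Transcripts of the mitochondrial genome, which encodes subunits of the respiratory chain and ATP synthase, were higher as a group with neratinib, with a median log2 fold change of 0.50 and 13 of 13 genes positive (camera adjusted p = 1.47e-07). Genes of cholesterol synthesis and uptake were lower as a group (median -0.42, 21 of 24 negative, camera adjusted p = 0.000669). Hypoxia and glycolysis genes (median -0.73, 22 of 24 negative, adjusted p = 0.00569), immediate early genes (median -0.77, 20 of 23 negative, adjusted p = 0.00886) and genes of the oligodendrocyte-progenitor-like glioblastoma state (median -0.46, 5 of 7 negative, adjusted p = 0.0289) were also lower. With an estimated correlation between genes in place of the preset value, none of these 5 calls held (unadjusted p = 0.0383 for mitochondrial, 0.0732 for cholesterol, 0.425 for hypoxia, 0.414 for immediate early and 0.207 for progenitor-like genes, adjusted p = 0.907 for each). The other 22 lists tested did not pass.

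Gene by gene, 0 of 14635 tested genes were called higher and 0 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (lowest adjusted p = 0.0619), while 1909 were higher and 3250 lower at an unadjusted p under 0.05. DESeq2 called 1003 higher and 2493 lower, and limma voom called 0 and 0, with 5328 genes at an unadjusted p under 0.05. All 3 neratinib libraries lay above all 3 vehicle libraries for 3045 genes and below them for 3910. Together these were 47.5% of the genes, against 10% expected by chance for each gene. The genes are not independent, so a gradient between libraries could separate many at once, and the excess was not tested. Without neratinib library 26, which stood farthest from the others, edgeR called 448 genes higher and 1984 lower.

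The direction of a gene's difference went with the GC content of its guides, used in place of transcript GC content. The Spearman correlation of log2 fold change with guide GC content was -0.572 over 12503 genes, across genes that are not independent replicates. It stayed at -0.516 without neratinib library 26. In that fit the median guide GC content was 51.25% for genes called higher and 61.25% for genes called lower, against 55% for all tested genes with guides. Slopes of a gene's log2 deviation from its mean over the libraries on guide GC content were taken per 10 percentage points. They were 0.33, 0.12 and 0.37 in vehicle libraries 21, 22 and 23 and -0.08, -0.13 and -0.61 in neratinib libraries 24, 25 and 26. Such slopes measure only differences between libraries, so the group means are equal and opposite by construction. Those means were 0.27 ± 0.13 and -0.27 ± 0.29 (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest that 20 assignments allow). List medians are therefore also given from the same edgeR fit with the library's GC slope as a covariate, an alternative chosen after seeing the data. Since the slopes of the groups did not overlap, that fit extrapolates between them. A second alternative chosen after seeing the data, removal of each library's trend on guide GC content, called 1 list higher (genes that increase when PI3K-AKT signalling falls, median 0.26, camera adjusted p = 0.0460) and 3 lower (cholesterol, hypoxia and cell cycle genes). Of single genes it called 389 higher and 457 lower by edgeR. Their adjusted p all lay just under the threshold, between 0.0487, the lowest of that fit, and 0.05. Mitochondrial genes have no guides and were left out of the trend removal, so their rise was not tested in that way. Their mean log2 deviation was -0.32, -0.13 and -0.30 in vehicle libraries 21, 22 and 23 and 0.17, 0.24 and 0.34 in neratinib libraries 24, 25 and 26. Genes with guides of 40 to 45% GC also had a positive median log2 fold change, 0.30.

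Targets of ATF4, the transcription factor whose translation increases when eIF2 alpha is phosphorylated, showed no shared direction when all 6 libraries were compared directly. Of 42 tested genes 14 were positive, 0 passed over all genes or when adjusted over the list alone, and the median was -0.26 (camera adjusted p = 0.812). XPOT, which exports tRNA from the nucleus, had the lowest p of the list, at 616 ± 10.8 CPM in vehicle and 823 ± 16.9 CPM in neratinib (SD, n = 3 each; log2 fold change 0.42 ± 0.09 SE, adjusted p = 0.0619), and was called with the GC trend removed (0.41, adjusted p = 0.0490). ATF4 itself had 336 ± 71.1 and 407 ± 196 CPM (log2 fold change 0.27 ± 0.37 SE, adjusted p = 0.606), and EIF2AK4 97.4 ± 2.14 and 98.6 ± 8.75 CPM (0.02 ± 0.11 SE, adjusted p = 0.913). Asparagine synthetase ASNS, named after its values were seen, had 111, 63.1 and 126 CPM in vehicle libraries and 230, 189 and 82.4 CPM in neratinib libraries 24, 25 and 26. Without neratinib library 26, ASNS (log2 fold change 1.07), MTHFD2 (0.83), CEBPG (0.62) and XPOT (0.41) were called higher and the amino acid transporter gene SLC7A5 (-0.90) and the proline synthesis gene PYCR1 (-0.64) lower by edgeR, with a list median of 0.01 (camera adjusted p = 0.226). These 6 were all the members called in that fit.

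The ATF4 targets were called higher with neratinib in the fit with the library GC slope as covariate, and not with the GC trend removed from each library (median 0.14, camera adjusted p = 0.860). With the covariate the list median was 1.17, 40 of 42 genes were positive, 8 passed over all genes and 29 were higher and 1 lower when adjusted over the list alone. The camera adjusted p was 2.62e-54 with the preset correlation and 0.0479 with an estimated correlation, the only list of 27 called both ways. The correlation estimated for the list was 0.052 in this fit, against 0.64 with no covariate. The call with an estimated correlation was lost whichever library was left out (adjusted p = 0.106 to 0.450). The fit called 12 genes higher and 0 lower, and 8 of the 12 were on the list: TRIB3, a pseudokinase induced by ATF4 (log2 fold change 2.60 ± 0.18 SE, adjusted p = 0.00481), ASNS (2.25 ± 0.17 SE, 0.00620), ATF4 (1.69 ± 0.15 SE, 0.0122), the mitochondrial folate enzyme gene MTHFD2 (1.66), CEBPG (1.19), SESN2 (2.83), NUPR1 (1.89) and DDIT3 (1.18). With the GC trend removed, CEBPG (0.84, adjusted p = 0.0487) was the only 1 of these 8 called, MTHFD2, TRIB3, ASNS, ATF4 and DDIT3 had 0.78, 0.83, 0.56, 0.39 and 0.25, and SESN2 and NUPR1 had -0.023 and -0.63 (adjusted p = 0.0702 to 0.984 for these 7). The other 4 of the 12 were GTPBP2 (1.40), MT1X (2.98), YARS (1.07) and EFNA1 (3.46). GTPBP2, YARS and EFNA1 had 0.18, -0.057 and 0.54 with the GC trend removed, none of them called, and MT1X had no guide GC content. For each of the 12 the CPM values of the groups overlapped. With no covariate MT1X (-1.05), NUPR1 (-0.66), SESN2 (-0.45), DDIT3 (-0.14) and GTPBP2 (-0.10) were negative. The others were positive, from 0.041 (TRIB3) to 0.74 (ASNS). Counts of MT1X are uncertain, since other metallothionein genes are near-identical in sequence. Without each library in turn the fit with the GC slope covariate called between 0 and 295 genes higher and between 0 and 208 lower, both highest without neratinib library 26 and both 0 without neratinib library 24 or 25. With the share of reads outside genes as the covariate instead, 0 genes were called and the ATF4 list was not (median 0.08, camera adjusted p = 0.156).

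**Figure D1:**
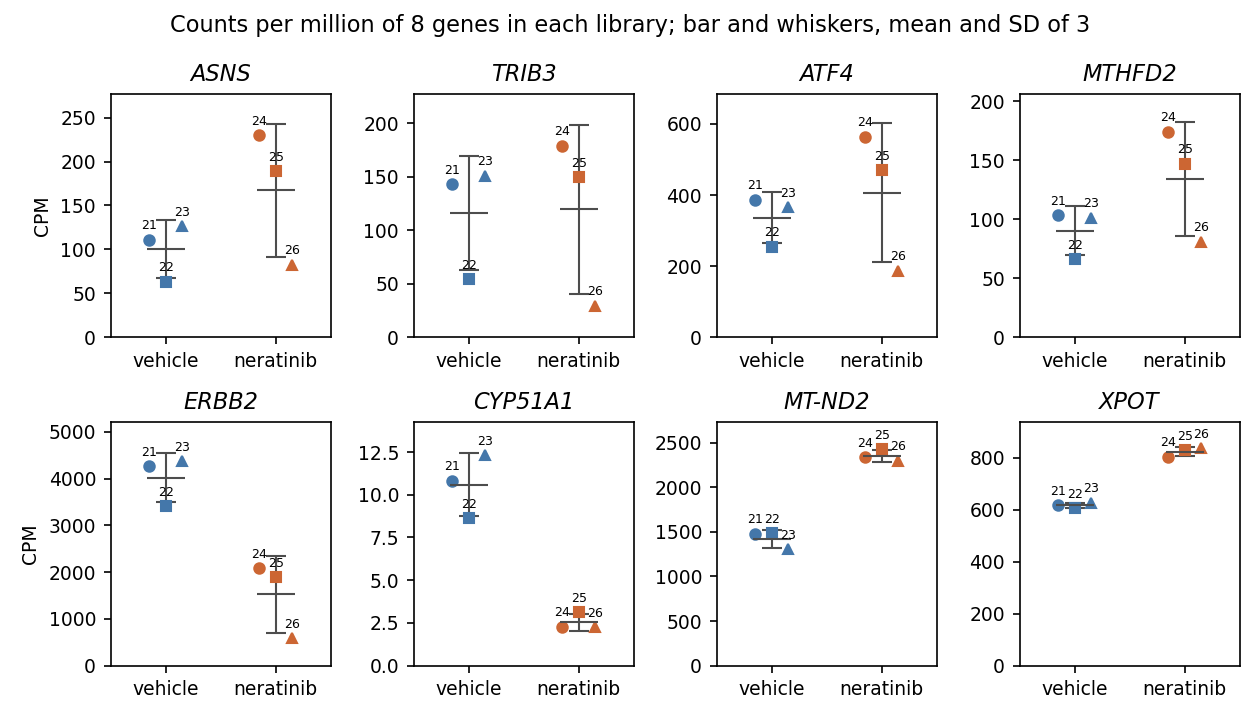
CPM of 8 genes (vertical axes, starting at 0) in each library, marked with its number, with the mean and SD of 3 libraries per group. ASNS, TRIB3, ATF4 and MTHFD2 were lowest of their groups in vehicle library 22 and neratinib library 26, while the neratinib libraries lay apart from vehicle for ERBB2, CYP51A1, MT-ND2 and XPOT.

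Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids and include ATF4 targets, had a median of 0.16 with 13 of 20 genes positive, and 1 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.332). The asparaginyl-tRNA synthetase gene NARS had 245 ± 3.40 CPM in vehicle and 319 ± 6.77 CPM in neratinib (SD, n = 3 each; log2 fold change 0.38 ± 0.09 SE, adjusted p = 0.0619), and 0.39 with the GC slope covariate. With that covariate the list median was 0.39, with 17 of 20 positive and 10 higher when adjusted over the list alone (camera adjusted p = 1.25e-11; adjusted p = 0.325 with an estimated correlation). With the GC trend removed it was 0.058 (adjusted p = 0.979). The list was also called higher without neratinib library 26 (0.24, adjusted p = 0.0350; adjusted p = 0.877 with an estimated correlation) and with the share of reads outside genes as covariate (0.32, 0.00156). Without neratinib library 24 its median was 0.057 (camera adjusted p = 0.695).

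Among the receptors that neratinib inhibits, ERBB2 had 4018 ± 523 CPM in vehicle and 1523 ± 814 CPM in neratinib (SD, n = 3 each; log2 fold change -1.40 ± 0.42 SE, adjusted p = 0.0732), with all neratinib libraries below all vehicle libraries. Its guides had 68.8% GC, and with the GC slope covariate its log2 fold change was 0.10 (adjusted p = 0.874), against -0.62 with the GC trend removed (adjusted p = 0.122). Without neratinib library 26 it was -1.01 (adjusted p = 0.0143). EGFR had 155 ± 26.1 and 148 ± 23.9 CPM (-0.06 ± 0.17 SE, adjusted p = 0.794). ERBB3, named by rule and not listed above as a target of neratinib, had between 6 and 17 counts per library and was below the count filter. Genes of RAS-ERK output had a median of -0.44, with 22 of 28 negative and 2 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.0737). With the GC slope covariate 18 of 28 were positive and the median was 0.17 (adjusted p = 0.184), and with the GC trend removed it was 0.0089 (adjusted p = 0.956). EPHA2, a receptor tyrosine kinase gene, had 386 ± 58.0 and 136 ± 54.5 CPM (-1.50 ± 0.31 SE, adjusted p = 0.0619). Its fold change was -0.45 with the covariate (adjusted p = 0.402) and -0.78 with the GC trend removed (adjusted p = 0.0487, a call). DUSP6, an ERK phosphatase gene induced by ERK, and SPRY4, a feedback inhibitor gene of the pathway, had log2 fold changes of -0.31 and -0.43 (adjusted p = 0.0954 and 0.0882), and -0.16 and -0.24 with the covariate (adjusted p = 0.682 and 0.651). Both were named after their values were seen, and had -0.25 and 0.39 with the GC trend removed (adjusted p = 0.150 and 0.206).

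Of the 23 immediate early genes, which growth factors induce within minutes, 9 were lower when adjusted over the list alone. ARC had 71.8 ± 17.3 CPM in vehicle and 17.5 ± 9.37 CPM in neratinib (SD, n = 3 each; log2 fold change -2.04 ± 0.45 SE, adjusted p = 0.0619). It had -0.50 with the GC slope covariate (adjusted p = 0.451) and -1.31 with the GC trend removed (adjusted p = 0.0487, a call). With the covariate the list median was 0.21 (camera adjusted p = 0.0565). The list's call was also lost without vehicle library 23 (median -0.47, adjusted p = 0.0760), without neratinib library 26 (-0.53, 0.0550) and with the GC trend removed (-0.15, 0.596). Genes that increase when PI3K-AKT signalling falls, among them ERBB2, had a median of 0.05 with 14 of 22 positive and 0 passing over the list alone (camera adjusted p = 0.332), and 0.27 with the covariate (adjusted p = 0.0354; adjusted p = 0.467 with an estimated correlation).

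Both lists of lipid synthesis genes had negative medians with and without the GC slope covariate. Of the 24 cholesterol genes 10 were lower when adjusted over the list alone, and the list median was -0.35 with the GC slope covariate (camera adjusted p = 1.05e-06; adjusted p = 0.467 with an estimated correlation). CYP51A1, the lanosterol demethylase of cholesterol synthesis, had 10.6 ± 1.85 CPM in vehicle and 2.55 ± 0.501 CPM in neratinib (SD, n = 3 each; log2 fold change -2.05 ± 0.23 SE, adjusted p = 0.0619). This gene had -1.61 with the covariate and -2.12 with the GC trend removed (adjusted p = 0.0487, a call). Members named after their values were seen did not all share this direction in the main comparison: MVD and DHCR7 had log2 fold changes of -2.21 and -1.27 (-0.56 and -0.51 with the covariate; -1.54 and -1.29 with the GC trend removed, adjusted p = 0.0487 for both), while HMGCS1, which acts early in the pathway, had 0.040 (-0.44 with the covariate and -0.25 with the GC trend removed, adjusted p = 0.148 for the latter). Fatty acid synthesis genes had a median of -0.30 with 10 of 13 negative and 3 lower when adjusted over the list alone (camera adjusted p = 0.0952), and -0.43 with the covariate (adjusted p = 0.00134; adjusted p = 0.467 with an estimated correlation), against -0.16 with the GC trend removed (adjusted p = 0.129). FASN, the fatty acid synthase gene, had 97.4 ± 42.7 and 16.8 ± 7.35 CPM (-2.54 ± 0.47 SE, adjusted p = 0.0619). FASN had -0.81 with the covariate (adjusted p = 0.336) and -2.34 with the GC trend removed (adjusted p = 0.0487, a call).

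Hypoxia and glycolysis genes, of which 5 were lower when adjusted over the list alone, had the opposite sign with the GC slope covariate (median 0.24, camera adjusted p = 0.0240; adjusted p = 0.587 with an estimated correlation). Their call was kept with the GC trend removed (median -0.48, adjusted p = 0.00284) and lost without vehicle library 23 (-0.70, 0.0527). ADM, the hypoxia-induced adrenomedullin gene, had 93.9 ± 45.8 CPM in vehicle and 32.7 ± 8.22 CPM in neratinib (SD, n = 3 each; log2 fold change -1.52 ± 0.40 SE, adjusted p = 0.0636), and vehicle library 22 had 42.1 CPM. ADM had -0.41 with the covariate (adjusted p = 0.778) and -0.61 with the GC trend removed (adjusted p = 0.184). Of the 13 mitochondrial transcripts 12 were higher when adjusted over the list alone, and the list median was 0.39 with the covariate (camera adjusted p = 5.61e-05; adjusted p = 0.445 with an estimated correlation). MT-ND2, a complex I subunit gene, had 1421 ± 102 and 2354 ± 66.1 CPM (0.73 ± 0.10 SE, adjusted p = 0.0619), and 0.72 with the covariate. Nuclear copies of mitochondrial genes share sequence with them, so these counts are uncertain by that share. The share of gene counts on mitochondrial genes was 3.16% ± 0.358 in vehicle and 4.43% ± 0.363 in neratinib (SD, n = 3 each; two-sided exact permutation p = 0.1).

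The other stress lists had no camera call. Endoplasmic reticulum chaperone and degradation genes had a median of 0.01 (10 of 20 positive, adjusted p = 0.902), heat shock genes 0.06 (9 of 16 positive, 0.902), NRF2 oxidative stress targets -0.18 (12 of 18 negative, 0.183), p53 targets -0.32 (12 of 19 negative, 0.515) and autophagy and lysosome genes 0.16 (14 of 24 positive, 0.800). Adjusted over the list alone, 0 members of the chaperone list passed, 1 heat shock gene was lower, 1 NRF2 target was higher and 7 lower, 2 p53 targets were higher and 5 lower, and 2 autophagy genes were higher and 2 lower. The members with the lowest p were SDF2L1 (log2 fold change -1.89), HSPB1 (-2.51), TKT (-1.28), CDKN1A (-1.12) and ATG12 (0.37). Of these HSPB1 (-1.70), TKT (-0.72) and ATG12 (0.61) were called with the GC trend removed (adjusted p = 0.0487 for each), and SDF2L1 (-1.16) and CDKN1A (-0.60) were not. With the GC slope covariate the 5 genes had -0.22, -0.29, -0.28, -0.54 and 0.31 in the order first given, and none was called (lowest adjusted p = 0.339). With the GC slope covariate the medians were 0.06, -0.25, -0.03, 0.15 and 0.30, and the autophagy and lysosome list, with 22 of 24 positive, had a camera adjusted p of 3.30e-10 (adjusted p = 0.252 with an estimated correlation). That fit also called the p53 targets higher (adjusted p = 0.00324), the chaperone list higher (0.0467) and the heat shock genes lower (0.0443), with adjusted p = 0.325, 0.420 and 0.467 with an estimated correlation. With the GC trend removed none of these 5 lists was called.

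Cell cycle genes had a median of -0.05 with 22 of 35 negative and 7 lower when adjusted over the list alone (camera adjusted p = 0.121). They were called lower without vehicle library 23 (-0.21, adjusted p = 0.00508), neratinib library 24 (-0.013, 0.0396) or 26 (-0.19, 0.00461; adjusted p = 0.877 with an estimated correlation). Their median was 0.12 without vehicle library 22 and 0.051 without neratinib library 25. The replication licensing gene CDT1 had 14.9 ± 1.52 CPM in vehicle and 3.70 ± 1.87 CPM in neratinib (SD, n = 3 each; log2 fold change -2.01 ± 0.36 SE, adjusted p = 0.0619). CDT1 had -0.91 with the GC slope covariate (adjusted p = 0.307) and -1.26 with the GC trend removed (adjusted p = 0.0487, a call). With the GC slope covariate 0 of 35 cell cycle genes were positive and the median was -0.50 (camera adjusted p = 1.13e-12; adjusted p = 0.467 with an estimated correlation), against -0.16 with the GC trend removed (adjusted p = 0.0140). Ribosomal protein genes had a median of -0.16 (37 of 56 negative, 0 over the list alone, adjusted p = 0.246), interferon-stimulated genes -0.03 (10 of 20 negative, 1 lower over the list alone, 0.957) and NF-kappaB targets -0.81 (16 of 17 negative, 0 over the list alone, 0.217). Their members with the lowest p were RPLP1 (log2 fold change -1.74), ISG15 (-3.14) and NFKB2 (-0.91). Of these RPLP1 (-1.64, adjusted p = 0.0498) and ISG15 (-2.36, 0.0487) were called with the GC trend removed, and NFKB2 (-0.24) was not. RPLP1, ISG15 and NFKB2 had -0.085, -0.87 and -0.019 with the GC slope covariate (adjusted p = 0.849, 0.676 and 0.985). The medians of the 3 lists with the covariate were 0.23, 0.22 and 0.63 (adjusted p = 1.53e-06, 0.330 and 0.0196; 0.587, 0.677 and 0.587 with an estimated correlation).

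Of the 4 glioblastoma state lists, the oligodendrocyte-progenitor-like list had 5 of 7 tested genes lower and 1 higher when adjusted over the list alone. Its call was lost without vehicle library 22 (adjusted p = 0.135), without neratinib library 25 (0.162) and with the GC trend removed (median 0.13, adjusted p = 0.797), and was kept with the GC slope covariate (-0.28, 0.0482; 0.587 with an estimated correlation). CSPG4, a proteoglycan gene of progenitor cells, had 55.1 ± 10.1 CPM in vehicle and 15.6 ± 4.28 CPM in neratinib (SD, n = 3 each; log2 fold change -1.82 ± 0.25 SE, adjusted p = 0.0619). CSPG4 had -1.34 with the GC slope covariate and -0.98 with the GC trend removed (adjusted p = 0.0487, a call). PDGFRA, the growth factor receptor gene on this list and on the fibroblast list, had 236 ± 17.2 and 332 ± 14.4 CPM (0.49 ± 0.10 SE, adjusted p = 0.0619), 0.50 with the covariate and 0.30 with the GC trend removed. Medians were -0.37 for the neural-progenitor-like (5 of 7 negative, camera adjusted p = 0.477), -0.10 for the astrocyte-like (8 of 14 negative, 0.873) and -0.09 for the mesenchymal-like list (9 of 14 negative, 0.626), with HES6 (-1.57) and FABP7 (0.43) the members of lowest p of the neural-progenitor-like and astrocyte-like lists. HES6 had -0.74 with the covariate and -0.73 with the GC trend removed, and FABP7 0.24 and 0.16, none of them called. With the covariate the mesenchymal-like median was 0.50 with 13 of 14 positive (camera adjusted p = 2.58e-09; adjusted p = 0.325 with an estimated correlation), against -0.10 with the GC trend removed (adjusted p = 0.797).

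Markers of other cell types were sparse and none of their lists was called by camera. Reads were counted on human genes only, and the host is not given in the sources used here. Low counts of these markers therefore do not measure cells of a non-human host. Of the 10 markers of red blood cells and lymphocytes 0 passed the count filter, and of the 14 markers of myeloid cells 2 did, with CD68 at 0.992 ± 0.267 CPM in vehicle and 0.549 ± 0.127 CPM in neratinib (SD, n = 3 each). Medians were -0.56 for the myeloid list, -0.57 for endothelial and mural cells (9 tested), 0.03 for neurons (7 tested), -0.34 for mature oligodendrocytes (2 tested) and 0.10 for fibroblasts (6 tested), with camera adjusted p of 0.626, 0.387, 0.957, 0.626 and 0.902. The members with the lowest p were ESAM (log2 fold change -1.88, at 0.492 CPM in vehicle), RBFOX3 (-1.05), CNP (-0.99) and PDGFRA. ESAM, RBFOX3 and CNP had -1.60, 2.55 and -0.14 with the GC slope covariate, and with the GC trend removed -1.38, -0.29 and -0.59, none of them called. CD68 (log2 fold change -0.85) had -0.0014 with the covariate and -0.52 with the GC trend removed, neither called. The endothelial and mural median was 0.085 with the covariate and -0.61 with the GC trend removed (camera adjusted p = 0.635 and 0.384). CNP is also on the progenitor-like list, and tumour cells of glioblastoma can express several of these genes. For 7 lists (tRNA synthetases, chaperones, heat shock, autophagy and lysosome, astrocyte-like, neurons, fibroblasts) the median, the mean and camera's direction differed in sign.

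**Figure D2:**
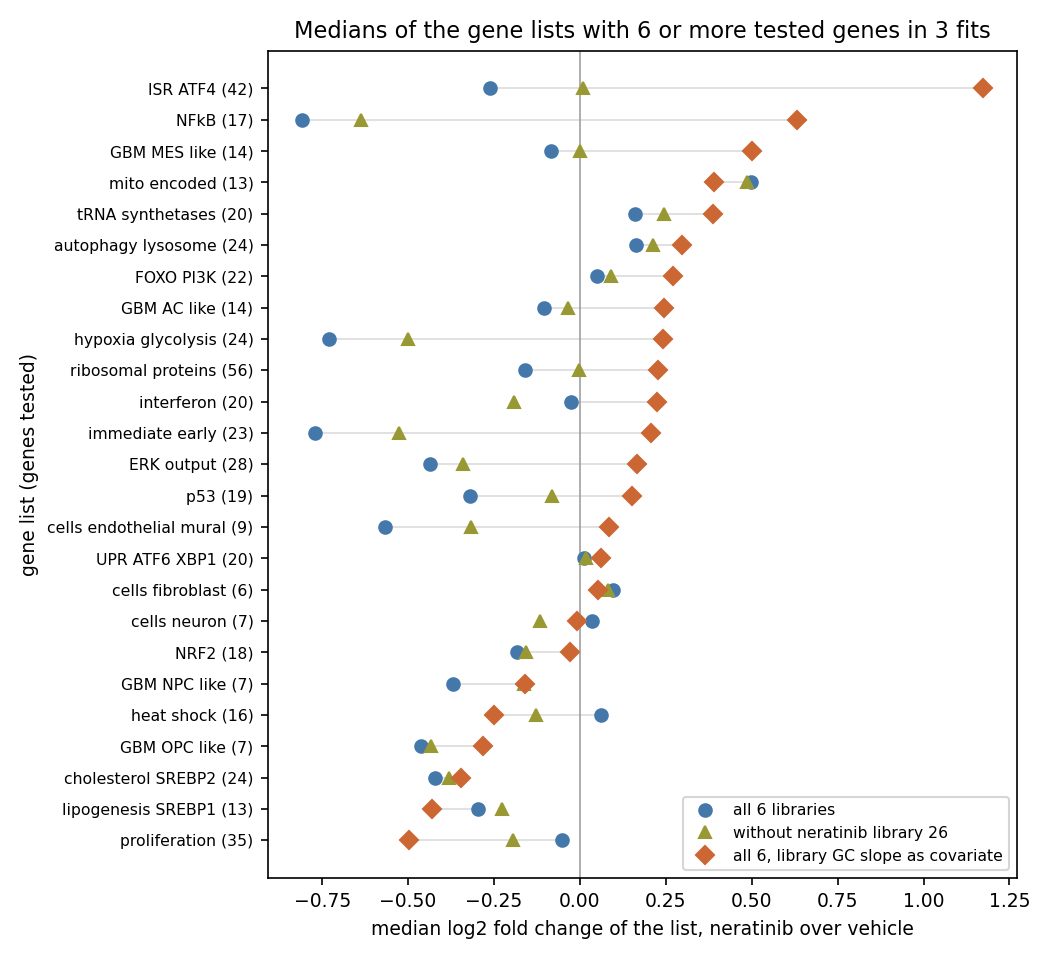
Median log2 fold change of neratinib over vehicle (horizontal axis) of each gene list with 6 or more tested genes (vertical axis, number tested in brackets), from all 6 libraries (circles), without neratinib library 26 (triangles) and with the library GC slope as covariate (diamonds). The ATF4 list had medians of -0.26, 0.01 and 1.17, and the cholesterol list -0.42, -0.38 and -0.35.

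The second part of the data was the guide library of the screens. TKOv3 is a pooled library of guide RNAs for knocking out human protein-coding genes with Cas9. Its index held 71090 guides of 20 nt, with 70948 guides for 18053 genes and 142 control guides against LacZ (96), luciferase (24) and EGFP (22). Of the genes, 17445 (96.6%) had 4 guides and the others fewer.

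In the plasmid pool, a single library with no replicate, 70876 guides were listed with 1 or more reads and 214 (0.301%) were not. For 17852 genes (98.9%) every guide was listed, and for 2 genes no guide was. The pool held 19382145 reads, with a median of 261 reads per guide, a 10th percentile of 146 and a 90th percentile of 418. The ratio of the 90th to the 10th percentile was 2.86 and the Gini coefficient 0.227. Fewer than 0.1 of the median reads were found for 809 guides, or 1.14% (95% exact binomial interval 1.06 to 1.22%). The median was 176 reads for control guides and 261 for gene guides.

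All 4 guides of EIF2AK4, the gene of GCN2, were present in the plasmid pool. The index places them on chromosome 15, with no genome build named: CGTTGCGGGTAGCTCTCCGG at 40226442 to 40226461 on the minus strand, with 226 reads (95% exact Poisson interval 197 to 257), GAACTGGCCAAGAAACACTG at 40235660 to 40235679 on the plus strand, with 239 reads (210 to 271), AAGGAAAGAAATGGCTAAGC at 40246164 to 40246183 on the plus strand, with 228 reads (199 to 260), and ATCGGGCAAACTCCTCAGGA at 40247942 to 40247961 on the plus strand, with 105 reads (85.9 to 127). Exon and intron positions are not given because no annotation of the index's build was used here. The guide ATCGGGCAAACTCCTCAGGA had 0.402 times the median, and its interval lay below those of the other 3. The most abundant guide of the pool, ACTCCTCGCCCTATTGGCCC for the bone protein gene BGLAP (chromosome 1, 156212037 to 156212056, plus strand), had 1306 reads, or 5.004 times the median. These intervals cover counting error only.

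**Figure D3:**
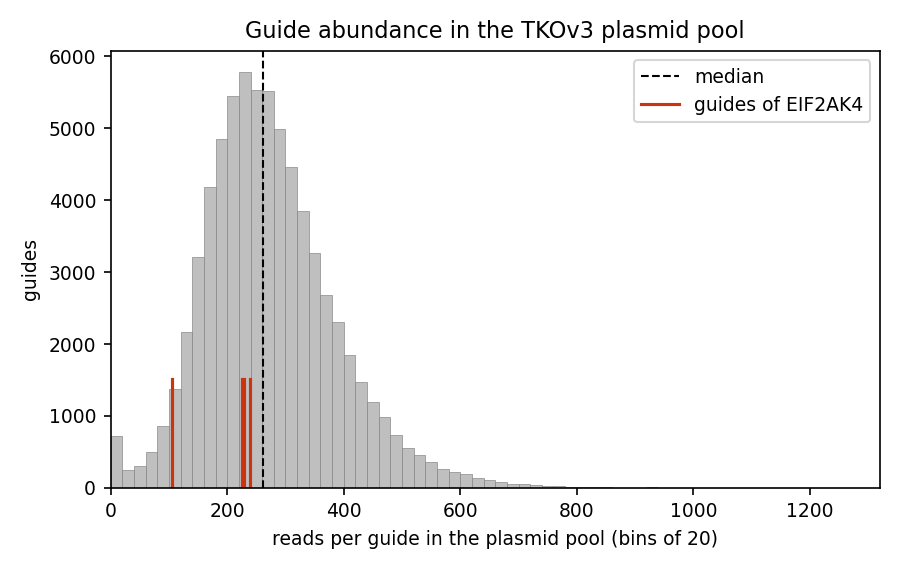
Number of guides (vertical axis) by reads per guide in the plasmid pool (horizontal axis, bins of 20 reads, unlisted guides at 0), with the median of 261 reads as a dashed line and the 4 guides of EIF2AK4 as short red lines. Those 4 guides had 226, 239, 228 and 105 reads.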

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

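The tests of the GC gradient against a gradient between libraries and against treatment as its whole cause, and the comparison of ATF4 with hypoxia genes, were chosen only after the results were seen.

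Reads outside annotated genes, which the report uses only as a covariate, made up 8.08% ± 0.632 of the reads in neratinib libraries and 7.10% ± 0.435 in vehicle libraries (SD, n = 3 each), with every neratinib library above every vehicle library. The two-sided exact permutation p was 0.1, the smallest that 20 assignments allow.

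Genes with GC-rich guides were low in the neratinib libraries, with a difference in mean GC slope of -0.55. The number of reads as such does not account for this, since thinning every library to the same total left 99.9% of the difference. Thinning leaves CPM unchanged on average, so this outcome was nearly fixed in advance. It does not cover other effects tied to library yield. A gradient between libraries that does not need the treatment is consistent with the data: the contrast of neratinib library 26 with 24 and 25 and the contrast of vehicle library 22 with 21 and 23, which share no library, correlated at r = 0.617 across 10906 genes that are not independent. As these libraries were picked by their GC slopes, a positive value partly restates that choice, but with the trend on guide GC removed from both contrasts r was 0.531 over 10289 genes. Neratinib as the whole or part of the cause stays open, because the slopes of the groups did not overlap, the labels name no batch, and the range of the vehicle slopes, 46.1% of the difference between the group means, rests on library 22 (8.30% between 21 and 23).

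Targets of ATF4 were called higher with neratinib in the fit with the library GC slope as covariate (median log2 fold change 1.17), but not with the GC trend removed from each library (median 0.14, camera adjusted p = 0.860). Random lists matched on GC content and expression argue against a by-product of the covariate that any genes of this GC content and expression would share. With the list itself counted, 0.01% reached its median, the smallest share that 10000 draws can give, and the highest random median was 0.23. The random genes were not chosen to vary together, as the list's genes did (estimated correlation 0.64 with no covariate and 0.052 with the GC slope covariate). A by-product for genes that vary together therefore stays open. A general rise of stress and hypoxia genes stays open: the median of the hypoxia and glycolysis list lay 0.93 lower in the same fit, but it was itself called higher (0.24, adjusted p = 0.0240), as were the NF-kappaB (0.63), mesenchymal-like (0.50), autophagy (0.30), p53 (0.15) and chaperone (0.061) lists, though none of these 6 calls held with an estimated correlation (adjusted p = 0.252 to 0.587). Other stress lists did not rise in that fit: heat shock genes were called lower by camera (-0.25, adjusted p = 0.0443; 0.467 with an estimated correlation). NRF2 targets had a median of -0.029 and were not called (adjusted p = 0.546). Overcorrection stays open: coefficients from the vehicle or the neratinib libraries alone gave medians of 1.35 and 1.09, but the joint coefficient is in effect a mean of these, each rests on vehicle library 22 or neratinib library 26, where the genes were low, and the bound set for them could not decide. Neratinib, including any activation of GCN2, stays open as untested, since groups whose slopes did not overlap cannot separate it from the gradient and the SF268 samples were not analysed here.

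The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 0 genes and the highest of the other splits 0, so that 10 of the 10 gave as many, which a count of 0 fixes in advance. At an unadjusted p under 0.05 the real split had 5159 genes and the highest other split 924. The real split called 5 lists by camera with the preset correlation and the highest other split 14, and 8 of the 10 splits gave as many. This cannot tell a structure of the samples from treatment, since each other split mixes the groups unequally and keeps part of any treatment difference. A preset correlation that is too low could also give such counts. With the GC slope covariate the real split called 12 genes and the highest other split 0, and 1 of the 10 splits gave as many. In that fit the median of the ATF4 list lay between -0.54 and 0.11 in the other splits, and 7 of those 9 were called by camera. Its preset-correlation p-values may therefore be too small here. The splits cannot settle this, because part of any treatment difference or gradient kept in them could also give such calls.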

How the results depend on the processing

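Settings with the GC slope or the share outside genes as covariate, the GC trend removed, genes limited to those with guide GC content, and voom quality weights were chosen after seeing the data. No paired analysis was possible because the columns carry no replicate numbers. The cause of a change was not tested unless stated. The main comparison called 0 genes higher and 0 lower. The counts were 1003 and 2493 with DESeq2, 130 and 1711 with no low count filter, 1119 and 2571 at an adjusted p under 0.1 (a looser threshold), 389 and 457 with the GC trend removed, 3494 and 4134 with voom quality weights, and 12 and 0 with the GC slope covariate. They stayed at 0 and 0 with limma voom, DESeq2 size factors, library size scaling, a mean of at least 50 counts, genes with guide GC content, the share outside genes as covariate, an adjusted p under 0.01 and an added fold change of at least 2. Leaving out 1 library, with or without the GC slope covariate, gave between 0 and 448 genes higher and between 0 and 1984 lower, the highest without neratinib library 26. With no covariate, leaving out any other library gave 0 and 0.

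Of the lists, 1 was called higher and 4 lower in the main comparison. Counts were 0 and 0 with an estimated correlation, 1 and 1 at a correlation of 0.05, 1 and 10 with no low count filter, 11 and 5 with the GC slope covariate and 3 and 8 with the share outside genes as covariate. Limiting genes to those with guide GC content gave 0 higher, because mitochondrial genes have no guides. Leaving out 1 library gave between 1 and 2 higher and between 4 and 5 lower, with changing members. Without vehicle library 23 hypoxia (adjusted p = 0.0527) and immediate early genes (0.0760) were lost and fatty acid synthesis (0.00878) and cell cycle genes (0.00508) gained. The fatty acid synthesis median was -0.40 there and -0.165 without vehicle library 21 (camera adjusted p = 0.156). Without vehicle library 22 the progenitor-like list (0.135) was lost and RAS-ERK output (0.00163) and NF-kappaB genes (0.000240) gained. The NF-kappaB median was -1.14 there and -0.35 without vehicle library 23 (camera adjusted p = 0.764). The progenitor-like list was called in 10 of 18 alternatives. The cholesterol list was called lower in 17 of 18 alternatives (medians -0.53 to -0.34) and the mitochondrial list higher in 15 of 16 (0.39 to 0.59). The exception for both was the estimated correlation. Most of the other alternatives used camera with the preset correlation on overlapping libraries, so they are not independent checks. With an estimated correlation neither call held in the main comparison (adjusted p = 0.907 for both). Nor did they hold with the GC slope covariate (0.467 for cholesterol, 0.445 for mitochondrial genes) or without neratinib library 26 (0.877 for both). The alternatives for the mitochondrial list do not include removal of the GC trend. The GC slope covariate turned camera's direction of 8 lists that were called before or after, with medians of 1.17 for ATF4 targets, 0.21 for immediate early, 0.061 for chaperone, 0.15 for p53, 0.24 for hypoxia, 0.23 for ribosomal, 0.63 for NF-kappaB and 0.50 for mesenchymal-like genes. It turned 4 more without a call (RAS-ERK output, NRF2, interferon and myeloid genes). The share outside genes as covariate turned that of ribosomal genes (0.14) with a call and 4 lists without one (ATF4 targets, chaperones, myeloid cells and neurons). Removing the GC trend turned camera's direction of 6 lists without a call, ATF4 targets (0.14) among them. The median of the ATF4 list lay between -0.50 and 1.31 over the fits that left out 1 library, and between 0.82 and 1.31 in those with the GC slope covariate, where its adjusted p with an estimated correlation was between 0.106 and 0.450.

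Of the 30 named genes, 25 kept their sign in every alternative. ATF4 turned in 1 of 17, EGFR in 3, EIF2AK4 in 5, ERBB2 in 1 (the GC slope covariate) and RBFOX3 in 1 of 16. In the plasmid pool the percentile ratio was 4.17 for the 95th over the 5th percentile, a wider span by construction, and the share of low guides was 1.01% under 20 reads and 1.98% under 0.25 of the median. Leaving out control guides moved none of these beyond their intervals. Control guides are 142 of the 71090 guides, so this outcome was nearly fixed in advance. Counts below the filter, such as those of ERBB3, are too few for a comparison.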

Other observations

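The genes in this paragraph and the next were named after their values were seen. UHRF1, which maintains DNA methylation through replication, had 53.05 ± 2.65 CPM in vehicle and 23.8 ± 2.68 CPM in neratinib (SD, n = 3 each; edgeR log2 fold change -1.15 ± 0.14 SE, adjusted p = 0.0619), and -1.28 with the GC slope covariate (adjusted p = 0.0823). UHRF1, LRP5 and IFI16 were called with the GC trend removed (-1.004, -1.65 and 1.01, adjusted p = 0.0487 for each). LRP5, a Wnt co-receptor gene, had 11.98 ± 1.43 and 2.24 ± 0.951 CPM (-2.42 ± 0.34 SE) and -1.36 with the covariate. IFI16, an innate DNA sensor gene, had 48.6 ± 8.45 and 83.4 ± 7.10 CPM (0.78 ± 0.15 SE) and 1.13 with the covariate. TXNIP, a gene that responds to glucose and nutrient state, had 1.56 ± 0.629 and 3.86 ± 1.33 CPM (1.31 ± 0.40 SE) and 2.01 with the covariate. At an unadjusted p under 0.05 in both fits were 644 genes, of which 340 were higher in both, 272 lower in both and 32 of opposite sign.

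Some autophagy genes stood out with the GC slope covariate without passing over all genes. WIPI1 had a log2 fold change of 1.45 (adjusted p = 0.0653), MAP1LC3B 1.01 (0.137) and GABARAPL1 0.94 (0.187), against 0.39, 0.44 and 0.28 with no covariate. With the GC trend removed they had 0.38, 1.25 and 0.058, of which MAP1LC3B was called (adjusted p = 0.0487). SQSTM1, which encodes an autophagy receptor, had -0.89 with no covariate, 0.17 with it and -0.84 with the GC trend removed, and the call of the list with the covariate was lost with an estimated correlation (adjusted p = 0.252). CHAC1, a glutathione-degrading enzyme gene induced by ATF4, had 1.93 ± 1.25 CPM in vehicle and 1.04 ± 0.845 CPM in neratinib (SD, n = 3 each) and a covariate log2 fold change of 3.22 (edgeR adjusted p = 0.0940), against -0.90 with no covariate and -0.00052 with the GC trend removed (adjusted p = 0.9997). HMOX1, the haem oxygenase gene, had 278 CPM in vehicle library 23 against 41.8 and 13.2 CPM in vehicle libraries 21 and 22 and between 5.22 and 13.2 CPM in the neratinib libraries.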
